A study of Mus musculus with 18 samples.

How the data were processed

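Total RNA of the left ventricular mid wall of male mice on the 129SVE background was sequenced by the submitters in 18 libraries, 3 in each of 6 groups: WT and KO at 3, 6 and 10 weeks of age. KO stands for knockout of the muscle LIM protein (MLP), the product of Csrp3. RNA was extracted from frozen tissue with the Qiagen RNeasy Plus Universal Mini Kit, and libraries were prepared with the NEBNext Ultra II RNA kit. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and the genome build GRCm38. The strand setting, the annotation release and the treatment of multimapping reads were not given in the sources used here. The values deposited by the authors were raw counts per Ensembl gene, with no normalization, and each table held 49315 genes. No column of per-sample values was left unused.

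Of the gene identifiers, 49056 matched GENCODE M21, which gave the symbols, and 259 did not. Start and end were identical to that annotation for 44858 of the matched genes, and 73 symbols were shared by more than 1 identifier. Library totals ran from 14980968 to 23001047 counts. A count of 0 over a whole group was read as an upper limit of 3 counts over that group, and such limits cover counting error only. No library was a copy of another: between replicates, the chi-squared statistic per degree of freedom ran from 7.56 to 70.5, and the correlation of log2 CPM (counts scaled to library size), taken across genes, from 0.966 to 0.989.

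Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15778 genes. Library sizes were scaled by TMM, and 1 robust quasi-likelihood (QL) model was fitted to all 18 libraries. The common dispersion was 0.0252. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over all genes tested in that contrast. A prior count of 2 was used for log2 CPM, as in the principal components and list tests. It was not used for the log2 fold changes of the fit. Every adjusted p given for a gene is from this edgeR fit, or from the same fit repeated without a library where the text says that 1 was left out. The 10 contrasts were KO against WT at each of the 3 ages, the difference of that genotype effect between each pair of ages, and the change from 3 to 6 and from 6 to 10 weeks within each genotype.

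Gene lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, with p adjusted over the 34 lists of a contrast. Lists covered stress and foetal cardiomyocyte genes, Z-disc and sarcomere genes, extracellular matrix and fibrosis genes, calcium handling, ion channels and gap junctions, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded messenger RNAs, the citrate cycle, branched-chain amino acid breakdown, glycolysis and glucose uptake, ATF4 and one-carbon stress genes, endoplasmic reticulum chaperones, cytosolic heat shock and autophagy genes, interferon-induced genes, complement and chemokine genes, proliferation, p53 targets, neonatal imprinted growth genes, clock genes and immediate early genes. The other lists held markers of fibroblasts, endothelium, mural cells, macrophages, T and NK cells, B cells, neutrophils, red cells, adipocytes, atrium, skeletal muscle, Schwann cells and nerve, and epicardium and mesothelium. Beside the calls over all genes, members were also counted with p adjusted over the list alone. With an estimated correlation, 2 calls of the 10 contrasts held: clock genes in KO against WT at 6 weeks, and ATF4 and one-carbon stress genes in the genotype effect at 10 against 3 weeks.

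The groups, contrasts, lists, threshold, alternatives and the rule for naming genes were set before the data were examined. In each genotype contrast the rule named Csrp3 and, among called genes with a mean of at least 2 CPM in the higher group and no overlap between the 3 KO and 3 WT values, the 10 largest increases and 10 largest decreases. Predicted loci were only counted. In the other contrasts it named the 5 largest in each direction, without the overlap condition for the genotype effects compared between ages. It also named up to 2 called members per direction of each list, and where no member was called the one with the smallest p. List members that lost their call when 1 library was left out are mostly not named in the text. Genes named outside the rule are given as chosen after their values were seen.

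The same steps were tested on simulated data made by changing 200 genes by a known fold in the 10-week comparison. At 1.5-fold, 2-fold and 4-fold edgeR recovered 25.4%, 77.6% and 97.0% of the changed genes, with 5 false calls among 138. DESeq2 1.42.0 made 24 false calls among 167 and limma voom 4 among 133. In the list test, the changed list had adjusted p = 1.8e-83, and 0 of 33 unchanged lists passed. Simulated genes were drawn independently of each other. The list test was therefore not checked for false calls where the genes of a list vary together.

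Alternatives tried were RLE size factors, no low count filter, a minimum mean CPM of 1 in a group, a DESeq2 Wald test, limma voom, a block for the replicate number, counts without mitochondrially encoded genes, a 1.5-fold minimum change, an adjusted p under 0.01, a fit to only the 2 groups compared, a fry rotation test for the lists, and each library left out in turn. Leaving out the 3 libraries rich in atrial transcripts, and leaving out genes called between WT at 10 and 6 weeks, were added after seeing the data. Replicate numbers did not pair the libraries: correlations between equally numbered libraries ran from -0.22 to 0.112, and 2 of 45 were above 0.1, so the block was used only as an alternative. Labels gave no batch, litter or sequencing date.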

Results

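Messenger RNA of the left ventricular mid wall was counted in 18 libraries of male 129SVE mice, to follow how expression changed with age as dilated cardiomyopathy progressed. Hearts labelled KO lack MLP by their label; MLP is the muscle LIM protein of the cardiomyocyte Z-disc, and mice without it are a model of dilated cardiomyopathy. There were 3 WT and 3 KO libraries at each of 3, 6 and 10 weeks, and WT and KO below follow the labels. Totals per library ran from 14980968 to 20384316 counts in WT at 3 weeks, 19118774 to 23001047 in WT at 6 weeks and 17859293 to 20026389 in WT at 10 weeks. In KO they ran from 17243640 to 21397675, 16778954 to 19123985 and 15873296 to 19533085 at 3, 6 and 10 weeks. Mitochondrially encoded genes took 15.2% ± 2.34, 12.0% ± 1.10 and 14.1% ± 0.846 of the counts in WT and 9.47% ± 1.67, 9.51% ± 0.733 and 8.37% ± 1.20 in KO at 3, 6 and 10 weeks (SD, n = 3). The first principal component held 37.6% of the variance, and its scores ran from -49.0 to -30.7 in the 9 WT libraries and from 15.2 to 66.6 in the 9 KO libraries. Levels are given as CPM, counts scaled to library size, with SD and n = 3. Log2 fold changes are given with an SE, which is the absolute log2 fold change divided by the square root of its QL F statistic. This SE is not estimated by the model itself, and values of different contrasts need not combine.

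Csrp3, the gene that encodes MLP, was not lower in the KO libraries. Csrp3 (ENSMUSG00000030470; GRCm38 chromosome 7, 48830398 to 48848033, minus strand) had a log2 fold change of KO against WT of 0.80 (SE 0.29, adjusted p = 0.081) at 3 weeks and 0.57 (SE 0.29, adjusted p = 0.19) at 6 weeks, and rose by 1.29 (SE 0.30, adjusted p = 0.0041) at 10 weeks. With 1 library left out the adjusted p of Csrp3 at 3 weeks ran from 0.026, without KO replicate 1, to 0.373, without KO replicate 2, and passed in 1 of 6 fits. These are counts over the whole gene, and which part of it was targeted is not given in the labels, so they do not show whether the protein is made. The genotype groups therefore rest on the labels.

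At 3 weeks, KO hearts already carried high levels of stress transcripts. Nppa, the precursor of atrial natriuretic peptide, rose from 248 CPM ± 76.4 to 2750 CPM ± 1160 (log2 3.47, SE 0.34, adjusted p = 8.4e-06). Acta1, the skeletal alpha-actin re-expressed in stressed ventricle, and Ankrd1, a stretch-responsive repeat protein of the sarcomere, rose by 3.51 (SE 0.30) and 2.81 (SE 0.47) on the log2 scale; both were chosen after their values were seen. Outside the stress and foetal cardiomyocyte list, Slc6a16, an orphan member of a neurotransmitter transporter family, rose from 0.0899 CPM ± 0.0393 to 38.3 CPM ± 5.87. Fgf6, a muscle growth factor also outside that list, rose from 0.371 CPM ± 0.0627 to 15.1 CPM ± 0.511. Idh2, the mitochondrial isocitrate dehydrogenase, fell from 1630 CPM ± 141 to 728 CPM ± 102.

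Of 15778 genes tested, 2419 differed between KO and WT at 3 weeks, 1365 higher and 1054 lower in KO, and 801 of them by over 2-fold. The 3 KO and 3 WT values did not overlap for 30.5% of all genes, where chance gives 10%. Among the largest increases were Plet1os, a transcript opposite Plet1 (no counts in WT, at least 141-fold higher), Syndig1 (log2 6.01, SE 0.78), the nuclear receptor Nr4a3 (5.28, SE 0.52), Col9a2 (4.78, SE 0.76), Pdzd3 (4.68, SE 0.42) and Lman1l (4.48, SE 0.49). Ankrd2 (7.48, SE 2.23) and Cnn1 (5.04, SE 1.41) also ranked there, but lost their calls when 1 library was left out (adjusted p up to 0.35 and 0.21). Among the largest decreases were Ifi202b (no counts in KO, at least 45.1-fold lower), the peptidase gene Naalad2 (-7.48, SE 0.45), the guanylate-binding protein gene Gbp2b (-7.26, SE 0.45), Ptprn2 (-6.26, SE 0.45), Tmprss13 (-6.12, SE 0.43), Sp110 (-5.49, SE 0.45), Tpm3-rs7 (-5.02, SE 0.28), the potassium channel gene Kcnj14 (-4.45, SE 0.29) and Selenbp2 (-4.19, SE 0.36). Klk1b22 (no counts in KO, at least 44.9-fold lower) lost its call when any of the 6 libraries was left out, with adjusted p up to 0.11. Ptprn2, Tpm3-rs7 and Kcnj14 were also low in WT at 10 weeks (at most 0.0493, 0.937 and 1.05 CPM). Their low level was thus not particular to KO. Naalad2, Gbp2b, Tmprss13 and Sp110 stayed lower in KO than in WT at 10 weeks. The count fell to 1309 without WT replicate 1 and to 1593 without WT replicate 2.

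Contractile stress genes and matrix genes moved up together at 3 weeks. Of 24 stress and foetal cardiomyocyte genes, 15 rose and 2 fell (17 and 2 adjusted over the list alone, median log2 1.80), with list adjusted p = 6.2e-09, and adjusted p = 0.11 with an estimated correlation. Edn3, encoding endothelin 3, rose by 4.30 (SE 0.52) and Acta2, smooth muscle actin, fell by 0.94 (SE 0.23). This list includes the atrial light chain genes Myl4 and Myl7, and KO replicate 3 held 118 CPM of Myl4 where the other two had 1.71 and 5.27. Of 29 Z-disc and sarcomere genes 17 rose and 0 fell (18 and 1 adjusted over the list alone, adjusted p = 2.1e-08, and adjusted p = 0.32 with an estimated correlation), among them the small heat shock protein gene Cryab (544 to 1540 CPM). Of 40 extracellular matrix and fibrosis genes 17 rose and 0 fell (26 and 0 adjusted over the list alone, adjusted p = 2.1e-08, and adjusted p = 0.32 with an estimated correlation). Cilp, a matrix protein of cardiac fibroblasts, rose by 2.30 (SE 0.39). Cytosolic heat shock and autophagy genes rose in 6 of 20 (9 adjusted over the list alone, adjusted p = 0.00024, and adjusted p = 0.32 with an estimated correlation), led by Hspb6 from 361 CPM ± 59.1 to 1430 CPM ± 178 and Hspb1 (1.79, SE 0.39). Of 25 interferon-induced genes 12 rose and 1 fell (13 and 1 adjusted over the list alone, adjusted p = 1.7e-06, and adjusted p = 0.32 with an estimated correlation). Irf7 was at 1.32 (SE 0.18), Ifit3 at 1.19 (SE 0.22) and Xaf1 at -1.39 (SE 0.22). Clock genes rose in 7 of 18 and fell in 0 (8 and 0 adjusted over the list alone, adjusted p = 0.0056, and adjusted p = 0.11 with an estimated correlation). Bhlhe40 was at 1.08 (SE 0.21). Endoplasmic reticulum chaperones rose in 5 of 18 (9 adjusted over the list alone, adjusted p = 0.0057, and adjusted p = 0.66 with an estimated correlation). Over the alternatives the chaperone adjusted p ran from 0.0054 to 0.66, and the fry test gave 0.099.

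Genes of mitochondrial energy supply moved down at 3 weeks, and the mitochondrially encoded share of counts was lower in KO as well (9.47% against 15.2%). Of 33 fatty acid oxidation genes 17 fell and 2 rose (22 and 2 adjusted over the list alone, adjusted p = 2.1e-08, and adjusted p = 0.32 with an estimated correlation). The electron transfer flavoprotein gene Etfb was at -0.87 (SE 0.15) and the thiolase Acaa2 at -0.71 (SE 0.11). Of 45 nuclear oxidative phosphorylation genes 18 fell and 0 rose (31 and 0 adjusted over the list alone, adjusted p = 5.6e-10, and adjusted p = 0.41 with an estimated correlation); Sdhc of complex II fell by 0.64 (SE 0.09). All 13 mitochondrially encoded messenger RNAs fell (13 adjusted over the list alone, adjusted p = 2.6e-08, and adjusted p = 0.32 with an estimated correlation), mt-Nd3 by 1.64 on the log2 scale (-1.64, SE 0.35). Citrate cycle genes fell in 7 of 18 (10 adjusted over the list alone, adjusted p = 4.6e-05, and adjusted p = 0.32 with an estimated correlation). Idh2 was at -1.16 (SE 0.11) and Sucla2 at -0.56 (SE 0.12). Branched-chain amino acid breakdown genes fell in 8 of 18 (9 lower and 2 higher adjusted over the list alone, adjusted p = 0.00099, and adjusted p = 0.39 with an estimated correlation). Bckdhb was at -0.73 (SE 0.12) and Aldh6a1 at -0.69 (SE 0.11). Genes of calcium handling (5 higher and 1 lower of 23; adjusted p = 0.47), ion channels and gap junctions (2 and 4 of 28; adjusted p = 0.43), glycolysis and glucose uptake (4 and 1 of 23; adjusted p = 0.71) and ATF4 and one-carbon stress (4 and 2 of 25; adjusted p = 0.32) did not pass as lists, and their counts adjusted over the list alone were 5 and 1, 4 and 4, 4 and 2, and 5 and 2. Within them Casq1, a calsequestrin, rose by 1.31 (SE 0.19), the channel gene Kcnd2 fell by 0.98 (SE 0.18), Pfkfb1 fell by 2.61 (SE 0.32) and the stress cytokine gene Gdf15 rose by 2.32 (SE 0.40).

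**Figure D1:**
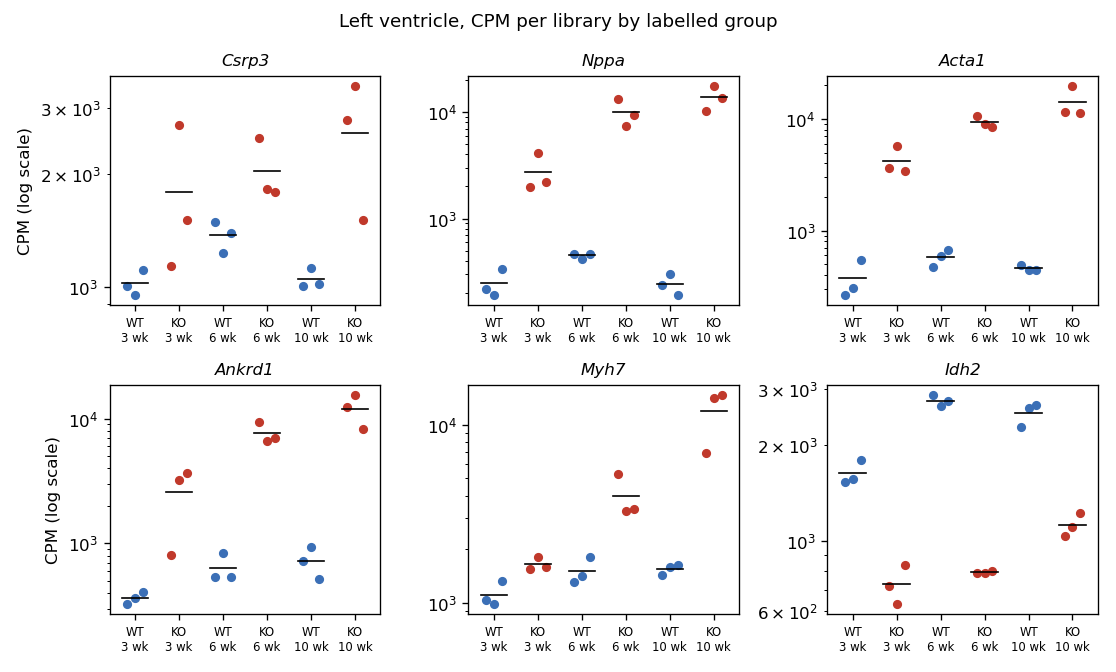
CPM (log axis) of Csrp3, Nppa, Acta1, Ankrd1, Myh7 and Idh2 in each of the 18 libraries by age in weeks; points are libraries (WT blue, KO red) and black lines are group means. Mean Nppa in KO was 2750, 10000 and 13800 CPM at 3, 6 and 10 weeks against 248, 450 and 243 CPM in WT, while Csrp3 was not lower in KO.

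At 6 weeks the KO hearts showed a broad fall of mitochondrial energy genes and a rise of matrix genes. The oxidative phosphorylation and matrix lists each had adjusted p = 0.1 with an estimated correlation. All 45 nuclear oxidative phosphorylation genes tested fell, with the muscle isoforms Cox8b from 1040 CPM ± 316 to 380 CPM ± 21.8 and Cox7a1 from 1080 CPM ± 263 to 402 CPM ± 7.95. Idh2 fell to 795 CPM ± 7.35 (log2 -1.79, SE 0.11). Nppa rose from 450 CPM ± 27.8 to 10000 CPM ± 3050 (4.48, SE 0.35), and Cilp from 4.12 CPM ± 0.933 to 81.9 CPM ± 3.77. The intermediate filament gene Des rose from 1850 CPM ± 214 to 4420 CPM ± 308.

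Between KO and WT at 6 weeks 3751 genes differed, 1729 higher and 2022 lower in KO, and 1275 of them by over 2-fold. The values did not overlap for 44.2% of all genes, where chance gives 10%. Large increases included Ces5a, a carboxylesterase gene (no counts in WT, at least 64.3-fold higher), Slc6a16 (log2 8.64, SE 0.37), Plet1os (7.69, SE 0.38), Syndig1 (6.97, SE 0.75), Serpinb1c (6.76, SE 0.67), Sprr1a (5.91, SE 1.08), Adamts8 (5.64, SE 0.89) and the lipoprotein receptor gene Lrp8 (5.29, SE 0.31). Ankrd2 (7.41, SE 1.90) and Cnn1 (5.79, SE 1.44) also ranked there, with adjusted p = 0.052 for each when WT replicate 1 was left out. Large decreases included Ptprn2 (-7.18, SE 0.45), Naalad2 (-6.59, SE 0.44), Tpm3-rs7 (-6.26, SE 0.34), Tmprss13 (-6.21, SE 0.40), Gbp2b (-6.16, SE 0.44), Sp110 (-5.42, SE 0.47), the oxidase gene Duox1 (-4.64, SE 0.50), Amd2 (-4.53, SE 0.59), Rtl3 (-4.47, SE 0.76) and Gdpd3 (-4.44, SE 0.20). Ptprn2 and Tpm3-rs7 were also low in WT at 10 weeks (at most 0.0493 and 0.937 CPM). Their low level was thus not particular to KO. Naalad2, Tmprss13, Gbp2b, Sp110 and Gdpd3 stayed lower in KO than in WT at 10 weeks. With any of the 6 libraries left out, the count ran from 2653 to 3377.

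Matrix, stress and interferon-induced genes were higher in KO at 6 weeks. Of 40 extracellular matrix and fibrosis genes 32 rose and 0 fell (34 and 0 adjusted over the list alone, median log2 1.06, adjusted p = 2.2e-17, and adjusted p = 0.1 with an estimated correlation). Fibroblast markers went 7 higher and 3 lower of 14 beside them (7 and 3 adjusted over the list alone, median log2 0.42, adjusted p = 0.082, from 0.008 with fry to 0.67 over the alternatives). Ltbp2, which binds elastic fibres, was at 2.96 (SE 0.52). Of 24 stress and foetal cardiomyocyte genes 15 rose and 2 fell (16 and 2 adjusted over the list alone, adjusted p = 1.5e-07, and adjusted p = 0.1 with an estimated correlation). Acta2 was at -2.23 (SE 0.24) and Myh7b at -1.24 (SE 0.17). KO replicate 3 held 436 CPM of the list member Myl4 where the other two had 6.45 and 4.12. Of 25 interferon-induced genes 14 rose and 1 fell (19 and 1 adjusted over the list alone, adjusted p = 3.6e-10, and adjusted p = 0.13 with an estimated correlation). Ifit3 was at 1.83 (SE 0.22), Ifit2 at 1.58 (SE 0.17) and Xaf1 at -0.92 (SE 0.22). Clock genes rose in 12 of 18 and fell in 2 (12 and 3 adjusted over the list alone, adjusted p = 0.00027, and adjusted p = 0.033 with an estimated correlation): the output genes Dbp and Ciart rose by 2.49 (SE 0.51) and 2.14 (SE 0.32), and Arntl, which encodes BMAL1, fell by 1.73 (SE 0.37). The labels give no time of day. Z-disc and sarcomere genes went both ways, 10 higher and 6 lower of 29 (11 and 6 adjusted over the list alone, adjusted p = 0.094), with myotilin (Myot) at 2.01 (SE 0.25) and cardiac troponin I (Tnni3) at -1.04 (SE 0.12). Over the alternatives its adjusted p ran from 0.043, without the 3 libraries rich in atrial transcripts, to 0.77.

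Lists of fuel use fell at 6 weeks, while the mitochondrially encoded share of counts was 9.51% in KO and 12.0% in WT. Nuclear oxidative phosphorylation genes fell in 45 of 45 (45 adjusted over the list alone, median log2 -0.81, adjusted p = 6.8e-31, and adjusted p = 0.1 with an estimated correlation). Fatty acid oxidation genes fell in 27 of 33 (28 adjusted over the list alone, adjusted p = 3.4e-17, and adjusted p = 0.1 with an estimated correlation). The thioesterase Acot1 was at -2.12 (SE 0.35) and Etfb at -1.47 (SE 0.15). Citrate cycle genes fell in 17 of 18 (17 adjusted over the list alone, adjusted p = 8.2e-13, and adjusted p = 0.1 with an estimated correlation), with fumarase (Fh1) at -0.80 (SE 0.10). Branched-chain amino acid breakdown genes fell in 12 of 18 (18 adjusted over the list alone, adjusted p = 7.5e-08, and adjusted p = 0.12 with an estimated correlation). Mccc1 was at -0.74 (SE 0.09) and Mccc2 at -0.75 (SE 0.11). Glycolysis and glucose uptake genes fell in 13 of 23 and rose in 2 (14 and 3 adjusted over the list alone, adjusted p = 0.0059, and adjusted p = 0.67 with an estimated correlation), with muscle enolase (Eno3) at -0.81 (SE 0.11) and Pfkp at 0.73 (SE 0.15). Mitochondrially encoded messenger RNAs fell in 5 of 13 (6 adjusted over the list alone, adjusted p = 0.0034, and adjusted p = 0.67 with an estimated correlation). mt-Co2 was at -1.10 (SE 0.25). Over the alternatives their adjusted p ran from 0.0029 to 0.67, and the fry test gave 0.063. Calcium handling genes (2 higher and 7 lower of 23; 3 and 9 adjusted over the list alone, adjusted p = 0.19) and ion channel and gap junction genes (3 and 9 of 28; 4 and 10 adjusted over the list alone, adjusted p = 0.19) did not pass; Hrc fell by 0.84 (SE 0.12) and the potassium channel subunit Kcne1 by 2.16 (SE 0.27). Over the alternatives their adjusted p ran from 0.0078 with fry to 0.49 and from 0.033 with fry to 0.67.

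At 6 weeks ATF4 and one-carbon stress genes rose in 8 of 25 and fell in 4 (11 and 4 adjusted over the list alone, adjusted p = 0.058): Mthfd2, a mitochondrial folate enzyme, rose by 2.81 (SE 0.28) and Gdf15 by 2.17 (SE 0.34), while the folate enzyme Aldh1l2 fell by 1.27 (SE 0.23). Over the alternatives the ATF4 adjusted p ran from 0.0047 with fry to 0.49. Cytosolic heat shock and autophagy genes rose in 6 of 20 and fell in 3 (6 and 3 adjusted over the list alone, adjusted p = 0.26). Hspb7 was at 1.14 (SE 0.17). Endoplasmic reticulum chaperones fell in 5 of 18 (5 adjusted over the list alone, adjusted p = 0.18). Hspa5 was at -0.98 (SE 0.17). Proliferation genes fell in 6 of 30 and rose in 2 (6 and 2 adjusted over the list alone, adjusted p = 0.03, and adjusted p = 0.77 with an estimated correlation). The kinetochore gene Cenpf was at -1.88 (SE 0.35) and the replication gene Mcm6 at 1.22 (SE 0.22). Over the alternatives the proliferation adjusted p ran from 0.0018 to 0.77, and the fry test gave 0.15.

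At 10 weeks stress transcripts were higher in KO than in WT. Nppa rose from 243 CPM ± 55.1 to 13800 CPM ± 3560 (log2 5.83, SE 0.38, adjusted p = 3.8e-08). Acta1 (4.94, SE 0.32), Ankrd1 (4.05, SE 0.50) and the slow myosin heavy chain gene Myh7 (2.94, SE 0.25) also rose, and were chosen after their values were seen. Myot, a Z-disc protein, rose from 35.2 CPM ± 3.75 to 408 CPM ± 90.8, and the fibrosis mediators Ccn2 and Tgfb2 rose by 4.84 (SE 0.80) and 4.14 (SE 0.61). Among fuel genes, Acot1 fell by 3.47 (SE 0.35), and the glucose transporter gene Slc2a1 rose from 9.30 CPM ± 2.28 to 45.8 CPM ± 15.7.

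Between KO and WT at 10 weeks 4625 genes differed, 2309 higher and 2316 lower in KO, and 1768 of them by over 2-fold. The values did not overlap for 40.5% of all genes, where chance gives 10%. Large increases included Ces5a (no counts in WT, at least 118-fold higher), Plet1os (log2 9.63, SE 0.48), Slc6a16 (9.01, SE 0.33), Sprr1a (8.91, SE 1.16), Psca (7.81, SE 0.56), Ankrd2 (7.80, SE 1.89), the transcription factor gene Pou3f1 (7.15, SE 0.70), Syndig1, the kinase gene Pak3 (6.16, SE 0.69) and Lrp8 (6.07, SE 0.31). Large decreases included Gbp2b, the calpain gene Capn11 and Guca1b, each with no counts in KO (at least 127-fold, 65.1-fold and 33.7-fold lower), Tmprss13 (-7.68, SE 0.43), Sp110 (-7.46, SE 0.57), Naalad2 (-6.47, SE 0.47), Gdpd3 (-6.31, SE 0.23), Eps8l1 (-5.93, SE 0.46), Chaer1 (-5.34, SE 0.55) and Rtn4r (-5.10, SE 0.52). Of these, Capn11, Guca1b and Eps8l1 were also among the largest increases from 6 to 10 weeks within WT. With any of the 6 libraries left out, the count ran from 3511 to 4787.

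The contractile and stress lists were higher in KO at 10 weeks. Of 24 stress and foetal cardiomyocyte genes 19 rose and 3 fell (19 and 3 adjusted over the list alone, median log2 2.84, adjusted p = 1.7e-10, and adjusted p = 0.053 with an estimated correlation). Acta2 was at -2.39 (SE 0.24). KO replicate 1 held 1150 CPM of the list member Myl4 where the other two had 3.99 and 9.98. Of 29 Z-disc and sarcomere genes 19 rose and 2 fell (20 and 3 adjusted over the list alone, adjusted p = 1.1e-09, and adjusted p = 0.15 with an estimated correlation). Synpo2l was at 3.33 (SE 0.48) and Tnni3 at -0.61 (SE 0.12). Of 40 extracellular matrix and fibrosis genes 29 rose and 0 fell (31 and 0 adjusted over the list alone, adjusted p = 3.2e-12, and adjusted p = 0.22 with an estimated correlation). Epicardial and mesothelial markers rose beside them in 8 of 10 (9 adjusted over the list alone, median log2 2.54, adjusted p = 3.8e-05, and adjusted p = 0.23 with an estimated correlation). ATF4 and one-carbon stress genes rose in 15 of 25 and fell in 0 (16 and 0 adjusted over the list alone, adjusted p = 2e-07, and adjusted p = 0.053 with an estimated correlation). Mthfd2 was at 3.73 (SE 0.30) and Gdf15 from 2.99 to 47.7 CPM. Cytosolic heat shock and autophagy genes rose in 11 of 20 (11 adjusted over the list alone, adjusted p = 0.00012, and adjusted p = 0.22 with an estimated correlation). Hspa1b was at 4.42 (SE 1.06), with 417 and 401 CPM in KO replicates 1 and 2, 27.7 CPM in KO replicate 3 and at most 21.3 CPM in WT at this age. Clock genes rose in 11 of 18 and fell in 3 (11 and 4 adjusted over the list alone, adjusted p = 0.0039, and adjusted p = 0.053 with an estimated correlation). Dbp was at 3.32 (SE 0.56) and Cry1 at -1.12 (SE 0.19), and Nr1d1 from 30.5 to 173 CPM. Endoplasmic reticulum chaperones fell in 7 of 18 (9 adjusted over the list alone, adjusted p = 0.032, and adjusted p = 0.89 with an estimated correlation). Dnajc3 was at -1.02 (SE 0.16). Over the alternatives their adjusted p ran from 0.016 to 0.89. Interferon-induced genes went 3 higher and 3 lower of 25 (3 and 3 adjusted over the list alone, adjusted p = 0.89). Xaf1 was at -1.78 (SE 0.23) and Mx2 at -1.03 (SE 0.27).

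Fatty acid oxidation, oxidative phosphorylation and citrate cycle genes were again lower in KO at 10 weeks, but none of these list calls held with an estimated correlation. The mitochondrially encoded share of counts was 8.37% in KO and 14.1% in WT. Fatty acid oxidation genes fell in 25 of 33 (28 adjusted over the list alone, adjusted p = 3.2e-12, and adjusted p = 0.15 with an estimated correlation). The uncoupling protein gene Ucp3 was at -2.72 (SE 0.40). Nuclear oxidative phosphorylation genes fell in 35 of 45 (39 adjusted over the list alone, adjusted p = 6.4e-10, and adjusted p = 0.41 with an estimated correlation). Ndufa1 was at -0.99 (SE 0.17). Citrate cycle genes fell in 11 of 18 (12 adjusted over the list alone, adjusted p = 7.3e-05, and adjusted p = 0.26 with an estimated correlation). Idh2 was at -1.17 (SE 0.11) and Sucla2 at -0.93 (SE 0.12). Mitochondrially encoded messenger RNAs fell in 10 of 13 (12 adjusted over the list alone, adjusted p = 7.8e-05, and adjusted p = 0.44 with an estimated correlation). mt-Co2 was at -1.35 (SE 0.25). Ion channel and gap junction genes fell in 13 of 28 and rose in 2 (13 and 3 adjusted over the list alone, adjusted p = 0.0034, and adjusted p = 0.22 with an estimated correlation). Kcne1 was at -2.62 (SE 0.33) and Kcnv2 at -2.24 (SE 0.42). Branched-chain amino acid breakdown genes (2 higher and 5 lower of 18; 2 and 5 adjusted over the list alone, adjusted p = 0.5), glycolysis and glucose uptake genes (4 and 3 of 23; 4 and 4 adjusted over the list alone, adjusted p = 0.79) and calcium handling genes (5 and 1 of 23; 7 and 2 adjusted over the list alone, adjusted p = 0.14) did not pass. Within them the transaminase gene Bcat2 rose by 1.18 (SE 0.12), the insulin-regulated glucose transporter gene Slc2a4 fell by 0.60 (SE 0.12) and Casq1 rose by 1.40 (SE 0.19). The calcium handling adjusted p over the alternatives ran from 0.0028 with fry to 0.31.

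**Figure D2:**
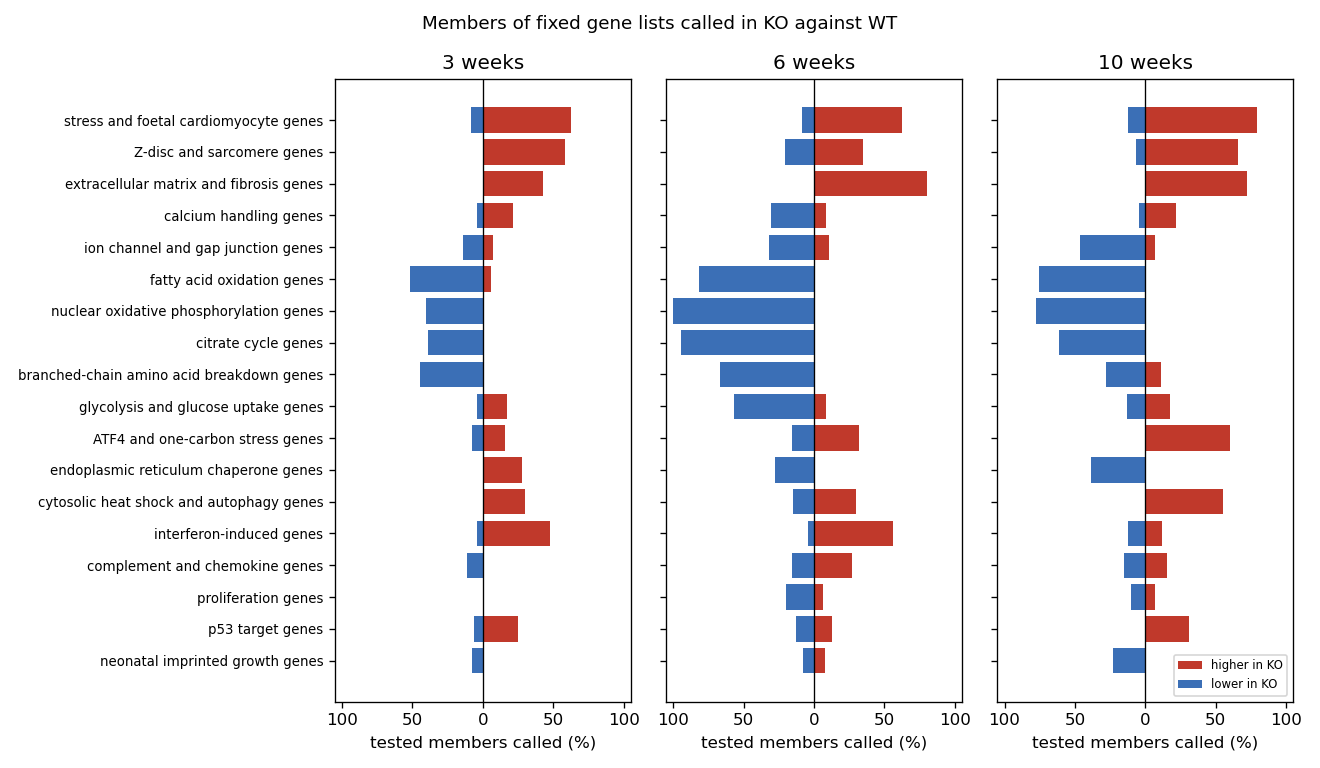
Percent of the tested members of 18 gene lists called higher in KO (red, right) or lower in KO (blue, left) at 3, 6 and 10 weeks. All 45 nuclear oxidative phosphorylation genes were lower at 6 weeks, and 17, 32 and 29 of 40 extracellular matrix genes were higher at 3, 6 and 10 weeks.

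The remaining pathway lists gave few calls in the genotype comparisons. Complement and chemokine genes went 0 higher and 3 lower, 7 and 4, and 4 and 4 of 26 at 3, 6 and 10 weeks (0 and 3, 9 and 7, and 4 and 4 adjusted over the list alone, adjusted p = 0.18, 0.48 and 0.5). Cxcl12 fell by 0.66 (SE 0.12) at 3 weeks and C4b rose by 1.56 (SE 0.38) at 6 weeks. Proliferation genes had 0 calls among 30 at 3 weeks (adjusted p = 0.93) and 2 higher and 3 lower at 10 weeks (2 and 3 adjusted over the list alone, adjusted p = 0.76). The p53 targets went 4 higher and 1 lower, 2 and 2, and 5 and 0 of 16 (4 and 1, 2 and 2, and 5 and 0 adjusted over the list alone, adjusted p = 0.32, 0.41 and 0.092), and Phlda3 rose by 1.24 (SE 0.15), 1.64 (SE 0.15) and 1.79 (SE 0.16). The p53 adjusted p over the alternatives ran from 0.0065, 0.016 and 6.8e-05 with fry to 0.48, 0.67 and 0.22. Neonatal imprinted growth genes went 0 higher and 1 lower, 1 and 1, and 0 and 3 of 13 (the same numbers adjusted over the list alone, adjusted p = 0.71, 0.93 and 0.76). The cell cycle inhibitor gene Cdkn1c was at -0.73 (SE 0.15) at 6 weeks and -1.50 (SE 0.15) at 10 weeks. Immediate early genes went 3 higher and 0 lower, 2 and 4, and 4 and 2 of 20 (4 and 0, 2 and 4, and 5 and 3 adjusted over the list alone, adjusted p = 0.12, 0.3 and 0.61). Nr4a3 was at 5.28 (SE 0.52) at 3 weeks and 3.63 (SE 0.50) at 10 weeks.

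Markers of other cell types gave 2 list calls at 3 weeks and 1 at 10 weeks. At 10 weeks, epicardial and mesothelial markers rose in 8 of 10 (9 adjusted over the list alone, median log2 2.54, adjusted p = 3.8e-05, and adjusted p = 0.23 with an estimated correlation). The uroplakin gene Upk1b was at 3.42 (SE 0.63) and the mucin gene Muc16 at 4.08 (SE 0.87). At 3 and 6 weeks this list had 0 and 1 calls (0 adjusted over the list alone at each age, adjusted p = 0.045 and 0.24, and at 3 weeks adjusted p = 0.66 with an estimated correlation). Over the alternatives the adjusted p at 3 weeks ran from 0.011 to 0.66. Schwann cell and nerve markers had 1 lower of 8 at each age, and adjusted over the list alone 0 higher and 1 lower, 1 and 1, and 0 and 1 (adjusted p = 0.012, 0.44 and 0.99, and at 3 weeks adjusted p = 0.38 with an estimated correlation). Gfra3 fell by 1.74 (SE 0.36) at 3 weeks. Fibroblast markers went 2 higher and 5 lower, 7 and 3, and 3 and 4 of 14 (2 and 6, 7 and 3, and 3 and 4 adjusted over the list alone, adjusted p = 0.18, 0.082 and 0.7): Lamc3 rose by 1.90 (SE 0.32), 3.97 (SE 0.31) and 1.94 (SE 0.28), and Scara5 fell by 1.80 (SE 0.37), 1.85 (SE 0.38) and 2.36 (SE 0.39). Over the alternatives the fibroblast adjusted p at 6 weeks ran from 0.008 with fry to 0.67. Endothelial markers went 0 and 0, 0 and 4, and 1 and 3 of 14 (0 and 0, 0 and 4, and 1 and 4 adjusted over the list alone, adjusted p = 0.46, 0.051 and 0.23). Cldn5 was at -1.32 (SE 0.25) at 6 weeks. The endothelial adjusted p at 6 weeks ran from 0.014 without the 3 libraries rich in atrial transcripts to 0.67, and fry gave 0.048. Mural cell markers went 2 and 1, 2 and 3, and 3 and 5 of 12 (2 and 3, 2 and 3, and 3 and 6 adjusted over the list alone, adjusted p = 0.36, 0.93 and 0.63). Cspg4 was at 1.56 (SE 0.23), 1.29 (SE 0.23) and 2.32 (SE 0.24). Macrophage markers went 1 and 1, 4 and 2, and 3 and 2 of 15 (1 and 0, 4 and 2, and 4 and 2 adjusted over the list alone, adjusted p = 0.93, 0.89 and 0.76). Mpeg1 was at 0.93 (SE 0.19) at 3 weeks and Cd163 at -1.47 (SE 0.27) at 6 weeks.

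Blood, fat, atrial and skeletal muscle markers did not pass as lists at any age, but some did under an alternative. Without the 3 libraries rich in atrial transcripts, red cell markers passed at 3 weeks (adjusted p from 0.0067 to 0.66 over the alternatives) and 6 weeks (0.028 to 0.77). There the adipocyte markers at 6 weeks passed with their direction turned round (0.014 to 1). Atrial markers passed at 10 weeks with fry (0.032 to 0.98). T and NK cell markers had 0 calls of 2 at each age (0 adjusted over the list alone, adjusted p = 0.75, 0.93 and 0.79), and B cell markers 0 higher and 1 lower, 0 and 0, and 1 and 0 of 7 (the same numbers adjusted over the list alone, adjusted p = 0.33, 1 and 0.22). Ighm was at -1.16 (SE 0.26) at 3 weeks. Neutrophil markers had 0, 1 and 0 lower of 3 (0, 1 and 0 adjusted over the list alone, adjusted p = 0.93, 0.48 and 0.76). Red cell markers had 0 calls of 6 at each age, and 1 higher and 4 lower at 3 weeks and 0 at the later ages adjusted over the list alone (adjusted p = 0.079, 0.34 and 0.24). Adipocyte markers went 0 and 0, 0 and 1, and 1 and 1 of 7 (0 and 0, 0 and 0, and 1 and 1 adjusted over the list alone, adjusted p = 0.87, 1 and 0.76). Cidea was at 0.41 (SE 0.10) and Lipe at -0.61 (SE 0.15) at 10 weeks. Atrial markers had 1, 1 and 2 higher of 9 (1, 1 and 2 higher and 0, 0 and 1 lower adjusted over the list alone, adjusted p = 0.63, 0.16 and 0.18), Nppa at each age. Skeletal muscle markers went 0 and 0, 1 and 1, and 2 and 0 of 6 (the same numbers adjusted over the list alone, adjusted p = 0.58, 0.93 and 0.76). In every list that passed in any of the 10 contrasts, the median, the mean and the test had the same sign; in 15 of the genotype results that did not pass they differed. In 1 KO library of each age the atrial transcripts of Sln, which encodes sarcolipin, reached 56.6, 190 and 506 CPM at 3, 6 and 10 weeks, and no other library was above 5.66 CPM.

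**Figure D3:**
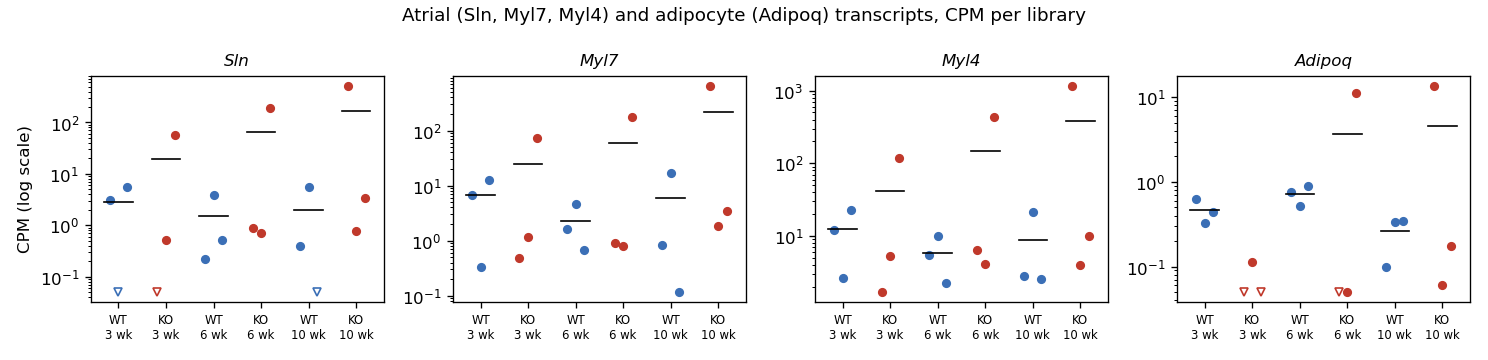
CPM (log axis) of the atrial transcripts Sln, Myl7 and Myl4 and the adipocyte transcript Adipoq in each of the 18 libraries by age in weeks; points are libraries (WT blue, KO red), black lines are group means, and open triangles mark libraries below the axis. In 1 KO library per age Sln was at 56.6, 190 and 506 CPM, and Adipoq was at 11.1 and 13.5 CPM in the 6-week and 10-week libraries of these.

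Many differences between KO and WT were shared by the 3 ages. In the same direction, 1059 genes were called at all ages, 591 higher (21.9 if the ages were independent) and 468 lower (19.8 if independent). The higher ones included Nppa, Slc6a16, Plet1os, Syndig1, Hspb6 and Phlda3, and the lower ones Idh2, Naalad2, Gbp2b, Sp110, Tmprss13 and Scara5. Genes called in opposite directions numbered 30 at 3 and 6 weeks, 72 at 6 and 10 weeks and 51 at 3 and 10 weeks, and 6852 genes were called at any age. Across genes, which are not independent replicates, log2 fold changes correlated with r = 0.718 (3 and 6 weeks), 0.609 (3 and 10) and 0.636 (6 and 10), each age having its own WT libraries.

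From 3 to 6 weeks the genotype effect shifted for lists that included extracellular matrix, chaperone and oxidative phosphorylation genes. Of 34 lists, 17 passed, 6 upward and 11 downward, and 0 held with an estimated correlation. Not all of the 17 are given below. The effect on Mthfd2 rose by 2.73 (SE 0.38, adjusted p = 0.0014) and that on the matrix gene Mfap4 by 1.65 (SE 0.28). The effect on Kcne1 fell by 2.10 (SE 0.36). That on the chaperone gene Hspa5 fell by 1.15 (SE 0.24), and lost its call without the 3 libraries rich in atrial transcripts. Of 15778 genes, 251 had an effect that differed between these ages, 78 upward and 173 downward. Among the largest were Ccn5 (2.75, SE 0.47) and Agt, the angiotensinogen gene (-3.20, SE 0.58). Of the others, Lrrc55 (2.43), Fam171b (2.17), Lamc3 (2.07), Nr4a3 (-4.25), Fam124b (-3.54), Adamts4 (-3.37) and Ogdhl (-3.06) each lost the call in at least 1 fit with a library left out. Extracellular matrix genes shifted up in 4 of 40 (10 adjusted over the list alone, adjusted p = 1.6e-08, and adjusted p = 0.39 with an estimated correlation). Fibroblast markers shifted up beside them in 3 of 14 (6 adjusted over the list alone, adjusted p = 1.5e-05, and adjusted p = 0.22 with an estimated correlation). Nuclear oxidative phosphorylation genes shifted down in 9 of 45 (40 adjusted over the list alone, adjusted p = 3.5e-24, and adjusted p = 0.22 with an estimated correlation), and endoplasmic reticulum chaperones down in 3 of 18 (7 adjusted over the list alone, adjusted p = 1.4e-05, and adjusted p = 0.4 with an estimated correlation). Fatty acid oxidation genes shifted down in 2 of 33 (15 adjusted over the list alone, adjusted p = 5.6e-09, and adjusted p = 0.25 with an estimated correlation), and citrate cycle genes down in 2 of 18 (10 adjusted over the list alone, adjusted p = 1.3e-08, and adjusted p = 0.22 with an estimated correlation). Glycolysis and glucose uptake genes shifted down in 1 of 23 (7 adjusted over the list alone, adjusted p = 4.7e-05, and adjusted p = 0.39 with an estimated correlation), and branched-chain amino acid breakdown genes down in 0 of 18 (2 adjusted over the list alone, adjusted p = 0.0029, and adjusted p = 0.48 with an estimated correlation). The count was 122, 116 and 426 without WT replicate 1, 2 or 3 of 3 weeks, 95 and 84 without WT replicate 1 or 3 of 6 weeks, 405 and 160 without KO replicate 2 or 3 of 3 weeks, and 126, 119 and 124 without KO replicate 1, 2 or 3 of 6 weeks. It was 160 without the 3 libraries rich in atrial transcripts.

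From 6 to 10 weeks the genotype effect shifted up for Z-disc, sarcomere and oxidative phosphorylation genes and down for interferon-induced genes. As a list, interferon-induced genes rose in WT and fell in KO. None of these list calls held with an estimated correlation. The effect on Slc2a1 rose by 2.11 (SE 0.29) and that on Bcat2 by 1.45 (SE 0.17), while those on Gbp3 and Rsad2 fell by 1.76 (SE 0.22) and 1.74 (SE 0.24). Effects differed for 908 genes, 493 upward and 415 downward. The largest shifts were Ptprn2 (11.22, SE 1.01), Kcnj14 (6.15, SE 0.42), Tpm3-rs7 (5.78, SE 0.66), Tent5b (5.77, SE 0.83), Eps8l1 (-6.65, SE 0.72), Hrasls (-4.20, SE 0.34), Unc5a (-4.17, SE 0.89) and Gal3st2c (-3.43, SE 0.65); Pou3f1 (5.07) and Ighg2c (-5.42) lost the call in at least 1 fit with a library left out. Ptprn2, Kcnj14, Tpm3-rs7, Eps8l1, Hrasls and Unc5a were also among the 5 largest changes of their direction from 6 to 10 weeks within WT. Interferon-induced genes shifted down in 9 of 25 (16 adjusted over the list alone, median -0.96, adjusted p = 6.6e-11, and adjusted p = 0.2 with an estimated correlation). Within WT they rose in 8 of 25 (15 adjusted over the list alone, median log2 0.53, adjusted p = 1.6e-09, and adjusted p = 0.47 with an estimated correlation), Rsad2 by 1.65 (SE 0.18). Within KO they fell in 5 (6 adjusted over the list alone, median log2 -0.30, adjusted p = 0.0054, and adjusted p = 0.56 with an estimated correlation). Z-disc and sarcomere genes shifted up in 11 of 29 (19 adjusted over the list alone, adjusted p = 1.3e-10, and adjusted p = 0.18 with an estimated correlation). Nuclear oxidative phosphorylation genes shifted up in 7 of 45 (38 adjusted over the list alone, adjusted p = 1.3e-13, and adjusted p = 0.42 with an estimated correlation). Within WT these fell in 20 of 45 (27 adjusted over the list alone, adjusted p = 2.7e-10, and adjusted p = 0.47 with an estimated correlation). Within KO 0 of 45 were called (0 adjusted over the list alone), and the list passed upward (median log2 0.14, adjusted p = 0.0011, and adjusted p = 0.71 with an estimated correlation). Citrate cycle genes shifted up in 1 of 18 (6 adjusted over the list alone, adjusted p = 0.00017, and adjusted p = 0.42 with an estimated correlation), and branched-chain amino acid breakdown genes up in 3 of 18 (6 adjusted over the list alone, adjusted p = 5.1e-06, and adjusted p = 0.3 with an estimated correlation). Glycolysis and glucose uptake genes shifted up in 4 of 23 (7 adjusted over the list alone, adjusted p = 0.00047, and adjusted p = 0.45 with an estimated correlation), and calcium handling genes up in 4 of 23 (7 adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.099 with an estimated correlation). ATF4 and one-carbon stress genes shifted up in 7 of 25 (10 adjusted over the list alone, adjusted p = 3.7e-06, and adjusted p = 0.099 with an estimated correlation), and stress and foetal cardiomyocyte genes up in 3 of 24 (8 adjusted over the list alone, adjusted p = 0.0089, and adjusted p = 0.46 with an estimated correlation). Cytosolic heat shock and autophagy genes shifted up in 2 of 20 (7 up and 1 down adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.42 with an estimated correlation), and proliferation genes up in 1 of 30 (1 adjusted over the list alone, adjusted p = 0.0056, and adjusted p = 0.79 with an estimated correlation). Epicardial and mesothelial markers shifted up in 2 of 10 (6 adjusted over the list alone, adjusted p = 0.0005, and adjusted p = 0.42 with an estimated correlation), and red cell markers up in 0 of 6 (0 adjusted over the list alone, adjusted p = 0.029, and adjusted p = 0.6 with an estimated correlation). The count was 513 and 493 without WT replicate 1 or 3 of 6 weeks, 566, 603 and 591 without WT replicate 1, 2 or 3 of 10 weeks, 460 without KO replicate 2 of 6 weeks, and 504 and 1598 without KO replicate 2 or 3 of 10 weeks. It was 517 when genes called between WT at 10 and 6 weeks were left out.

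Between 3 and 10 weeks the genotype effect grew for ATF4 and one-carbon stress genes. Their effect rose in 9 of 25 and fell in 0 (13 and 0 adjusted over the list alone, median log2 0.96, adjusted p = 5.4e-08, and adjusted p = 0.041 with an estimated correlation). Mthfd2 was at 3.65 (SE 0.40). The effect on Nppa rose by 2.35 (SE 0.44) and that on Myh7, chosen after its values were seen, by 2.38 (SE 0.34), while that on Acot1 fell by 3.14 (SE 0.47). Endoplasmic reticulum chaperones shifted down in 6 of 18 (12 adjusted over the list alone, adjusted p = 2.9e-06, and adjusted p = 0.47 with an estimated correlation). Manf was at -1.69 (SE 0.34). Of 34 lists, 15 passed, 11 upward and 4 downward, and only the ATF4 list held with an estimated correlation. Not all of the 15 are given here. Effects differed for 909 genes, 445 upward and 464 downward. The largest shifts were Ptprn2 (10.30, SE 1.01), Kcnj14 (7.96, SE 0.44), Psca (6.70, SE 0.96), Pak3 (5.52, SE 0.91), Eps8l1 (-5.86, SE 0.76), Unc5a (-5.04), Hrasls (-3.99, SE 0.40) and Cnmd (-3.40, SE 0.75), and Pou3f1 (4.60) and Gbp10 (-3.59) lost the call in at least 1 fit with a library left out. In KO, Ptprn2 and Eps8l1 were at most 0.491 and 0.854 CPM at every age. In WT at 10 weeks Ptprn2 was at most 0.0493 CPM and Eps8l1 between 14.1 and 25.4 CPM, so these shifts came mainly from a change within WT. The count was 570 and 552 without WT replicate 1 or 2 of 3 weeks, 558 without WT replicate 3 of 10 weeks, and 553 and 1497 without KO replicate 2 or 3 of 10 weeks. It was 593 when genes called between WT at 10 and 6 weeks were left out.

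From 3 to 6 weeks the proliferation and extracellular matrix lists fell in WT hearts and the oxidative phosphorylation list rose. None of these list calls held with an estimated correlation. Proliferation genes fell in 19 of 30 (28 adjusted over the list alone, median log2 -1.97, adjusted p = 4.1e-24, and adjusted p = 0.23 with an estimated correlation). Ccna2 was at -2.62 (SE 0.44) and Kif11 at -2.60 (SE 0.40). Extracellular matrix genes fell in 17 of 40 (22 adjusted over the list alone, adjusted p = 1.5e-13, and adjusted p = 0.29 with an estimated correlation). Fibroblast markers fell in 2 of 14 (2 adjusted over the list alone, adjusted p = 0.031, and adjusted p = 0.45 with an estimated correlation). Col3a1 was at -1.16 (SE 0.16), and nuclear oxidative phosphorylation genes rose in 10 of 45 (30 adjusted over the list alone, adjusted p = 1.5e-13, and adjusted p = 0.29 with an estimated correlation). The foetal growth factor gene Igf2 fell by 1.17 (SE 0.16), and Idh2 rose by 0.76 (SE 0.11). In all 818 genes differed, 464 higher and 354 lower at 6 weeks: Cpxm2 (3.13, SE 0.34), the ketone body enzyme gene Bdh1, Ogdhl (2.32, SE 0.43) and Inmt (1.75, SE 0.30) rose most, and the mitotic genes Aspm (-3.14, SE 0.38), Troap (-2.99, SE 0.56), Ckap2 (-2.90, SE 0.54) and Cep55 (-2.86, SE 0.57), with Mxd3 (-2.83, SE 0.52), fell most. D7Ertd443e (1.98, SE 0.48) also ranked among the increases but lost its call without replicate 2 of 3 weeks. The count was 278, 199 and 1313 without replicate 1, 2 or 3 of 3 weeks, and 213 and 305 without replicate 1 or 3 of 6 weeks.

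From 6 to 10 weeks several genes in WT hearts went from near absence to clear expression, or the reverse. Eps8l1 rose by 5.66 (SE 0.43), Hrasls by 4.87 (SE 0.26), Unc5a by 4.56 (SE 0.61) and Capn11 by 7.47 (SE 0.79), and Guca1b was at least 42.7-fold higher, with no counts at 6 weeks. Ptprn2 fell by 9.40 (SE 0.56), Kcnj14 by 6.27 (SE 0.33), Tpm3-rs7 by 4.93 (SE 0.30), Vwc2 by 4.28 (SE 0.89) and Hmga1b by 4.16 (SE 0.24). In all 1383 genes differed, 575 higher and 808 lower at 10 weeks. Interferon-induced genes rose in 8 of 25 (15 adjusted over the list alone, adjusted p = 1.6e-09, and adjusted p = 0.47 with an estimated correlation). Rsad2 was at 1.65 (SE 0.18), and nuclear oxidative phosphorylation genes fell in 20 of 45 (27 adjusted over the list alone, adjusted p = 2.7e-10, and adjusted p = 0.47 with an estimated correlation). Proliferation genes fell in 9 of 30 (13 adjusted over the list alone, adjusted p = 6e-07, and adjusted p = 0.47 with an estimated correlation). The count was 555 and 754 without replicate 1 or 3 of 6 weeks, and 722, 742 and 762 without replicate 1, 2 or 3 of 10 weeks.

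**Figure D4:**
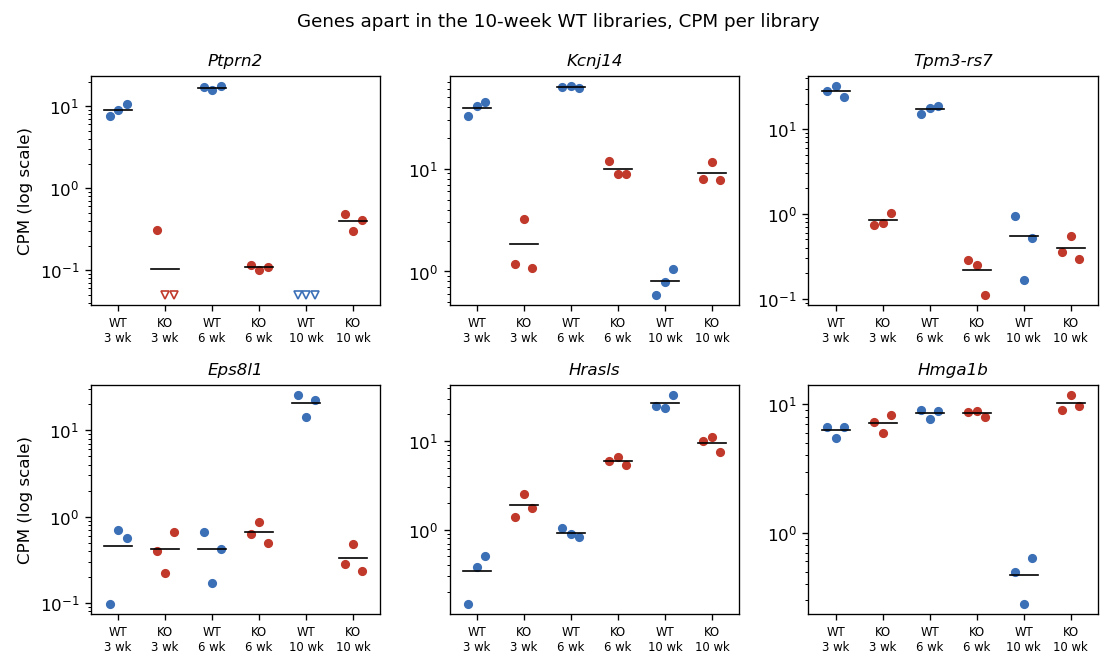
CPM (log axis) of Ptprn2, Kcnj14, Tpm3-rs7, Eps8l1, Hrasls and Hmga1b in each of the 18 libraries by age in weeks; points are libraries (WT blue, KO red), black lines are group means, and open triangles at 0.05 mark libraries below 0.05 CPM. The 3 WT libraries at 10 weeks lie apart from the 6 younger WT libraries for these genes: Eps8l1 was between 14.1 and 25.4 CPM in them and at most 0.708 CPM in the younger ones.

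In KO hearts the change from 3 to 6 weeks also ran through proliferation genes. These fell in 27 of 30 (28 adjusted over the list alone, median log2 -2.18, adjusted p = 3.8e-27, and adjusted p = 0.077 with an estimated correlation). Ccnb1 was at -3.83 (SE 0.50) and Hmmr at -3.80 (SE 0.77). Endoplasmic reticulum chaperones fell in 9 of 18 (12 adjusted over the list alone, adjusted p = 6.3e-06, and adjusted p = 0.61 with an estimated correlation), and clock genes rose in 10 of 18 and fell in 4 (10 and 5 adjusted over the list alone, adjusted p = 0.0045, and adjusted p = 0.077 with an estimated correlation). Nppa rose by a further 1.87 (SE 0.31). In all 1829 genes differed, 843 higher and 986 lower at 6 weeks: Bdh1 (3.91, SE 0.35), Ccn5 (3.41, SE 0.34), Cpxm2 (3.35, SE 0.31) and Psca (3.29, SE 0.44) rose most, and Nr4a3 (-5.21, SE 0.52), Adamts4 (-4.03, SE 0.49) and Kif2c (-3.86, SE 0.57) fell most beside Ccnb1 and Hmmr. Sprr1a (3.55, SE 0.82) lost its call without replicate 3 of 3 weeks. The count was 1195 without replicate 3 of 3 weeks, 1089 and 1185 without replicate 1 or 3 of 6 weeks, and 1099 without the libraries rich in atrial transcripts.

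From 6 to 10 weeks the heat shock and sarcomere lists rose in KO hearts and the extracellular matrix list fell. None of these list calls held with an estimated correlation. Hspa1b rose by 6.24 (SE 1.19), but reached 417 and 401 CPM in KO replicates 1 and 2 and 27.7 CPM in replicate 3. Cytosolic heat shock and autophagy genes rose in 13 of 20 and fell in 1 (17 and 2 adjusted over the list alone, adjusted p = 6.4e-08, and adjusted p = 0.35 with an estimated correlation). Z-disc and sarcomere genes rose in 12 of 29 (15 adjusted over the list alone, adjusted p = 3.3e-09, and adjusted p = 0.35 with an estimated correlation). Myot was at 2.26 (SE 0.25), and extracellular matrix genes fell in 14 of 40 and rose in 2 (21 and 3 adjusted over the list alone, adjusted p = 0.00019, and adjusted p = 0.55 with an estimated correlation). Col3a1 was at -1.15 (SE 0.16) and Ccn2 at 3.59 (SE 0.75). In all 1996 genes differed, 1028 higher and 968 lower at 10 weeks: beside Hspa1b, Hspa1a (5.99, SE 1.26), Abra (4.32, SE 0.54) and Cldn23 (3.98, SE 0.85) rose most, and Col26a1 (-2.71, SE 0.30), Snai3 (-2.57, SE 0.55), Lrrc17 (-2.52, SE 0.39) and Gal3st2c (-2.41, SE 0.50) fell most. Atf3 (4.44, SE 1.08) and Plekhh1 (-2.40, SE 0.66) lost their calls without replicate 2 of 6 weeks. The count was 983 and 1307 without replicate 2 or 3 of 6 weeks, 1084 without replicate 2 of 10 weeks, 1241 without the libraries rich in atrial transcripts and 874 in a fit to these 2 groups only.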

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

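The tests of the genes that differ within WT between 6 and 10 weeks, of the Csrp3 counts and of the atrial transcripts were chosen only after those results were seen.

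The genotype effect differed between ages, by a test of the difference itself, in 251 genes and 17 lists from 3 to 6 weeks, 908 genes and 13 lists from 6 to 10 weeks, and 909 genes and 15 lists from 3 to 10 weeks. Values below are log2 differences of the effect, and 1 list held with an estimated correlation, ATF4 and one-carbon stress genes from 3 to 10 weeks (median 0.96). From 3 to 6 weeks the largest were Ccn5 at 2.75, Mthfd2 at 2.73, Lrrc55 at 2.43, Fam171b at 2.17, Lamc3 at 2.07, Nr4a3 at -4.25, Fam124b at -3.54, Adamts4 at -3.37, Agt at -3.20 and Ogdhl at -3.06. From 6 to 10 weeks they were Ptprn2 at 11.22, Kcnj14 at 6.15, Tpm3-rs7 at 5.78, Tent5b at 5.77, Pou3f1 at 5.07, Eps8l1 at -6.65, Ighg2c at -5.42, Hrasls at -4.20, Unc5a at -4.17 and Gal3st2c at -3.43. From 3 to 10 weeks they were Ptprn2 at 10.30, Kcnj14 at 7.96, Psca at 6.70, Pak3 at 5.52, Pou3f1 at 4.60, Eps8l1 at -5.86, Unc5a at -5.04, Hrasls at -3.99, Gbp10 at -3.59 and Cnmd at -3.40. Lrrc55, Fam171b, Lamc3, Nr4a3, Fam124b, Adamts4, Ogdhl, Pou3f1, Ighg2c and Gbp10 each lost the call in at least 1 fit with a library left out. Ptprn2 and Eps8l1 were at most 0.491 and 0.854 CPM in KO at every age, so their shifts came mainly from a change within WT. Nppa differed by 2.35 from 3 to 10 weeks. The next genes were chosen after their values were seen. Myh7 differed by 1.54 from 6 to 10 and 2.38 from 3 to 10 weeks. From 3 to 6 and from 6 to 10 weeks, Fkbp5 differed by -2.90 and 3.29, Zbtb16 by -2.67 and 3.96, Hif3a by -2.77 and 3.12, Mt1 by -2.19 and 2.08, Mt2 by -1.78 and 3.51, and Cdkn1a by -2.44 and 2.95. From 3 to 10 weeks Mt2 differed by 1.73.

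Other splits of the same libraries were fitted in the same way. For the effect at 6 against 3 weeks, 3 of 40 splits gave as many genes, the real one included (251, highest other 2449). For 10 against 6 weeks 2 of 40 did (908, highest other 1290), and for 10 against 3 weeks 3 of 40 (909, highest other 5463). By this count chance was not excluded, but the other splits with as many genes all left the labels of 1 age whole or exchanged all of them, which keeps the genotype effect of that age. They follow this structure of the samples, are no distribution without change, and so do not speak for chance either. The splits that mixed the labels of both ages, 29, 34 and 32 of the 40, had 0 calls with edgeR. The real split had 2403, 3433 and 3131 genes at an unadjusted p under 0.05. The mixed splits were not counted by another tool. Mixing puts KO and WT libraries in 1 group, so the genotype effect adds to the spread within groups. Few calls were therefore bound to result, and they do not argue against chance. In each of the other 7 comparisons 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real count and the highest other were 2419 and 0, 3751 and 0, and 4625 and 0 for KO against WT at 3, 6 and 10 weeks. They were 818 and 0 for WT at 6 against 3 weeks, 1383 and 0 for WT at 10 against 6, 1829 and 1 for KO at 6 against 3, and 1996 and 71 for KO at 10 against 6. Splits with 0 calls had them with edgeR, and the real splits for KO against WT had 4546, 5474 and 6233 genes at an unadjusted p under 0.05. Here too the other splits mixed the real groups, so their low counts do not argue against chance.

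Between WT at 6 and 10 weeks 70 genes were called over 8-fold, among them Ptprn2, Kcnj14, Eps8l1 and Hrasls, against 7 between WT at 3 and 6 weeks and 26 between KO at 6 and 10 weeks. An exchange of the 10-week WT and KO libraries was argued against: of 120 genes over 8-fold between KO and WT at both earlier ages, 94 (78.3%) had the 10-week WT mean nearer the 6-week WT mean. The rest, Ptprn2 among them, did not, so their earlier difference between KO and WT need not hold against the 10-week WT libraries. A different genetic background of the 10-week WT animals may account for the pattern, and the ratio of 2.69 to the larger other age comparison lay between the limits set for and against it. Age stays open as well: 8 of the 70 genes (11.4%) changed the same way by over 2-fold in KO. Ptprn2 and Tpm3-rs7 were at most 0.115 and 0.288 CPM in KO at 6 weeks, and so had little room to fall further. How many of the 70 genes this holds for was not counted. Age and the origin of the animals cannot be told apart here, since all 10-week WT libraries share both.

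Csrp3 was not lower in KO, and Csrp3 was at 1.29 in KO against WT at 10 weeks. The related genes Csrp1 and Csrp2 together held 8.46% of the Csrp3 counts in the KO library where their share was highest. This met the limit set against their reads as a source. Reads of these genes assigned to Csrp3 would not be in that share, and the treatment of multimapping reads is not given. The share therefore cannot exclude this source. An exchange of all KO and WT labels was argued against: of the called stress and foetal cardiomyocyte genes at least 86.4% were higher in KO at each age, and Nppa was at 1980 CPM or more in each KO library and 467 CPM or less in each WT library. A transcript of the targeted allele counted over its remaining exons is a candidate explanation, but whole-gene counts (lowest KO library 1.11 times the WT mean of its age) do not test it. No biological explanation beyond the KO label was tested.

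In 1 KO library of each age Sln, Myl7 and Myl4 were high: replicate 3 at 3 and 6 weeks and replicate 1 at 10 weeks. Atrial tissue in these libraries may account for this: markers not used to pick them (Tbx5, Stard10, Angpt1 and Fgf12) were above both other libraries of the group in 11 of 12 pairs (91.7%, where chance gives 33.3%). In the other 6 KO libraries, 12 of 54 pairs with the 9 atrial markers were over 2-fold above the WT mean (22.2%). Of these, 6 were for Nppa, 5 for Dkk3 and 1 for Fgf12, between the limits set for and against atrial gene expression in all KO hearts. Sln, Myl7, Myl4, Tbx5, Stard10 and Angpt1 had 0 such pairs, and Sln was at most 3.33 CPM there. For these 6 markers the values argue against a rise of over 2-fold in all KO hearts. For Nppa, Dkk3 and Fgf12 it stays open. Of the atrial list, Myl4, Myl7 and Nppa are also in the stress list, and Nppa was called with the 3 libraries rich in atrial transcripts left out. How the tissue was dissected is not given beyond the mid wall.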

How the results depend on the processing

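Leaving out the 3 libraries rich in atrial transcripts, and leaving out genes called between WT at 10 and 6 weeks, were chosen after seeing the data.

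Under RLE size factors, limma voom, the replicate block, a minimum mean CPM of 1 and no mitochondrial genes, the 10 counts stayed within 1.5 times their value; with the block, whose replicate correlations ran from -0.22 to 0.112, KO against WT gave 2362, 3717 and 4557 genes. Order below: KO against WT at 3, 6 and 10 weeks; the genotype effect at 6 against 3, 10 against 6 and 10 against 3 weeks; WT at 6 against 3 and 10 against 6; KO at 6 against 3 and 10 against 6. A 1.5-fold minimum gave 450, 946, 1347, 14, 149, 190, 47, 146, 259 and 179 genes, and an adjusted p under 0.01 gave 1187, 2344, 2938, 59, 298, 340, 202, 523, 839 and 800, with 591 at all 3 ages; both are stricter by construction. Without 1 library, counts ran from 1309 to 2542, 2653 to 3377, 3511 to 4787, 84 to 426, 460 to 1598, 552 to 1497, 199 to 1313, 555 to 1185, 1089 to 1620 and 983 to 2634. No low count filter gave 880, 1550 and 1479 for the genotype effects between ages and 1404 for WT at 6 against 3 weeks. DESeq2 gave 651 and 1478 for the first 2 of these effects and 1325 for WT at 6 against 3 weeks. A fit to only the 2 groups compared gave 1495 and 2463 in WT, and 874 for KO at 10 against 6 weeks, from fewer samples. The cause was not tested for the filter and DESeq2. Without the 3 libraries rich in atrial transcripts, 160 effects differed between 3 and 6 weeks, and 1099 and 1241 genes in the 2 KO age comparisons, from fewer samples. Without genes called between WT at 10 and 6 weeks the effects at 10 against 6 and 3 weeks numbered 517 and 593, from fewer genes.

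With an estimated correlation camera called 0, 1 and 0 lists for KO against WT and 0, 0 and 1 for the genotype effects between ages, and fry called 7 and 4 lists for the effects at 6 against 3 and 10 against 3 weeks; the cause was not tested. Of 102 list results for KO against WT, 65 kept their side with an estimated correlation and 37 lost the call. With fry 87 kept their side, 10 gained a call and 5 lost it, and without the libraries rich in atrial transcripts 96 kept it and 5 gained a call. There the adipocyte markers at 6 weeks turned round (adjusted p = 0.014), and the cause was not tested. Over the named genes, 1928 results without 1 library kept their side, 275 lost the call and 5 gained it. In simulated changes of 1.5-fold at this depth and n = 3, with 200 genes changed in all, edgeR recovered 25.4%. The real KO against WT comparisons called 2419 genes or more. With more calls the adjusted p is less strict, so recovery there may differ.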

Other observations

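The genes in the next paragraph, and Xist and Ddx3y, were chosen after their values were seen, and no test below was.

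The stress- and hormone-responsive genes Fkbp5, Mt1 and Cdkn1a were higher in KO at 3 and 10 weeks and lower at 6 weeks. Fkbp5, a co-chaperone of the glucocorticoid receptor, was at 1.76 (SE 0.19), -1.14 (SE 0.20) and 2.15 (SE 0.20) on the log2 scale in KO against WT at 3, 6 and 10 weeks. The metallothionein gene Mt1 was at 1.39 (SE 0.18), -0.80 (SE 0.18) and 1.28 (SE 0.18), and the cell cycle inhibitor gene Cdkn1a at 0.88 (SE 0.21), -1.56 (SE 0.22) and 1.39 (SE 0.21). All these passed, as did each of them with any 1 library left out. Mt2 was at 2.74 (SE 0.23), 0.97 (SE 0.23) and 4.48 (SE 0.27), higher at each age. The transcription factor gene Zbtb16 was at 0.40 (SE 0.30, adjusted p = 0.42), -2.27 (SE 0.31) and 1.69 (SE 0.31), and did not pass at 3 weeks. Hif3a, of the hypoxia-inducible factor family, did not follow this course: it was at -0.93 (SE 0.27, adjusted p = 0.021), -3.70 (SE 0.34) and -0.58 (SE 0.36, adjusted p = 0.25), and at 3 weeks it lost the call without WT replicate 2, WT replicate 3 or KO replicate 2 (adjusted p up to 0.105).

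In KO replicate 3 of 6 weeks Xist had 2132 counts (118 CPM), and in the other 17 libraries from 0.175 to 1.71 CPM. Ddx3y, on the Y chromosome, had 425 counts (23.5 CPM) in that library. It is labelled male and is 1 of the 3 libraries rich in atrial transcripts (Sln 190 CPM), with 11.1 CPM of the adipocyte transcript Adipoq.

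A hypothesis set beforehand was that a segment linked to the targeted gene differs between KO and WT animals. Within 10 Mb of Csrp3, 25 of 165 genes (15.2%) were called at all 3 ages, against 950 of 14502 (6.55%) on other chromosomes, a ratio of 2.31 (Fisher exact test, two-sided p = 0.000101). A linked segment may thus contribute to the calls near Csrp3, and neighbouring genes are not independent. The genes named above were not sorted by whether they lie in this window. A second hypothesis was that blocks of chromosome differ between the WT animals of 10 and 6 weeks. Neighbouring calls were 1.30 times the permuted number for WT at 10 against 6 weeks and 1.40 times for WT at 6 against 3 weeks. The ratio of these, 0.929, was under 1, the limit set beforehand against this hypothesis. It also lay within its spread over permutations (0.117) of 1, a margin that was not part of that limit. Permutations place the calls at random, so this spread is not the error of the observed ratio. The hypothesis therefore stays open.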
